A study of Mus musculus with 18 samples.

How the data were processed

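RNA was measured by sequencing in inguinal fat, a subcutaneous white adipose depot, of male C57BL/6J mice. The mice had received Lewis lung carcinoma (LLC) cells, a mouse lung tumour line, or phosphate-buffered saline (PBS) under the skin. The 18 libraries fall into 4 groups by the labels' titles: PBS at day 7 (n = 4), LLC at day 7 (n = 5), PBS at day 21 (n = 4) and LLC at day 21 (n = 5). The labels call day 7 pre-cachexia and day 21 cachexia, the wasting of fat and muscle that accompanies some tumours. Per the labels' protocols, messenger RNA was enriched through its poly(A) tail and made into libraries with the NEBNext Ultra kit. The protocols name no strand-marking step, so reads of overlapping and antisense genes may be shared. The titles number the mice or samples within each group and say no more about them, so p-values measure the spread between these samples, which may be partly technical.

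The authors' deposited data are 1 table per day, each with 9 libraries and 21899 gene IDs. The submitters' processing notes name fastp 0.23.0, which trims reads, RSEM without a version, which divides reads among transcripts by estimation, and the builds mm10 and GRCm38. The aligner, the annotation release and the authors' comparison tool are not given in the sources used here. The deposited count columns were taken as RSEM expected counts rounded to whole numbers by the authors: 100% of values were whole, and 176 entries had a TPM above 0 beside a count of 0. The TPM columns were scaled by the authors for transcript length and library total, and were used here only in alternatives. The deposited log2 column is the authors' ratio of mean TPM in LLC over PBS, with 0.001 in place of a mean of 0. The deposited p-value and FDR columns come from the authors' own comparison and were used only to set the authors' deposited table beside the results. All per-sample value columns were assigned to a sample by name. No deposited gene ID was left out of library sizes for lack of a name, although 30 IDs carry no symbol. Gene coordinates are 1-based positions on GRCm38 from the GENCODE annotation, which matched 21806 of the 21899 IDs.

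RSEM estimates how reads divide between near-identical genes. Values of Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Ifit3b and its neighbours, the mast cell proteases Cma1, Mcpt4 and Tpsb2, and histone genes such as H2bc4 are therefore less certain than those of single-copy genes. Enrichment through the poly(A) tail also captures most histone messages poorly, since these usually lack one.

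Total counts per library ran from 14566155 (day 7 LLC library 5) to 18969387 (day 7 LLC library 4), and 3562 gene IDs had 0 counts throughout. Samples sharing a group differed in their counts by more than sampling noise: the lowest chi-square per gene over the 32 pairs was 15.9, so each counted as a separate replicate.

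Counts were compared with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter on low counts, quasi-likelihood fits at the installed default settings and two-sided tests with Benjamini-Hochberg adjustment at 0.05. LLC was compared with PBS in the 9 libraries of each day. The difference of the tumour effect between days, and day 21 against day 7 within PBS and within LLC, came from 1 fit of all 18 libraries with 4 group means. CPM are TMM-scaled counts per library of standard size, from the libraries of the day in the within-day comparisons and from all 18 libraries elsewhere and in the plots. Errors are SD for CPM and SE for log2 fold changes. That SE is approximate: the size of the log2 fold change divided by the square root of the quasi-likelihood F statistic. Otop1 and Ucp1 were also tested by exact two-sided permutation of the mean log2(CPM + 1), where the smallest p that 4 against 5 libraries allows is 0.0159.

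The 27 gene lists (functions of fat, signalling responses, and markers of other cell types that a fat sample could hold) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. Camera asks whether a list moves relative to all other genes. It was repeated with a correlation estimated per list, with fry of the same package, and by exact permutation of a score per library, the mean of each member's log2 CPM relative to its mean over all 18 libraries. For each list the number of members past the threshold is also given adjusted over the list alone. A further 6 lists were drawn up after the data were seen (mast cell, lymphatic endothelium, histone, chylomicron and enterocyte, major urinary protein and hepatocyte, and tumour cell candidates).

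Genes to be named were set by rule: Otop1 (the gene in the series title), Ucp1, Adipoq and Lep; the 10 largest rises and 10 largest falls among genes past the threshold with at least 1 CPM in a group, groups that did not overlap and a proper symbol, or, where fewer than 5 passed in a direction, the 5 with the smallest p, named as not past it; and up to 4 members per list with the smallest p. For the between-day comparisons the rule takes the 5 genes with the smallest p in each direction under the same conditions. Groups, tests, the 27 lists, this rule and most alternatives were fixed before the data were examined.

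The numbers in the titles were checked for pairing across PBS and LLC by correlating the deviations from group means of samples with the same number. At day 7 these correlations were 0.207, 0.12, 0.531 and 0.19 for numbers 1 to 4. Each was over 0.1, so the numbers were treated as pairs there. A replicate block was fitted as the paired alternative, without LLC library 5, which has no partner. For numbers 2 and 4, however, another LLC library correlated more closely. The value of 0.531 joined the libraries with the highest skeletal muscle scores of that day, so the pairing is an assumption. The pairing rests on these data alone, since the labels state no shared litter, batch or day.

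On simulated counts with 200 changed genes, the day 7 procedure recovered 77% of 2-fold and 96% of 4-fold changes (13445 genes; 6 false among 179 calls). The day 21 procedure recovered 25% and 67% (13564 genes, 7 false among 99 calls). The test of the difference between days recovered 24% and 78% (13975 genes, 6 false among 108 calls). Each gene was drawn independently, without the differences between libraries that many genes share. These rates therefore do not cover the effect of libraries that stand apart.

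Alternatives covered DESeq2 1.42.0 and its size factors, other filters on low counts, robust fits, a minimum fold change, 1 fit of all libraries, the replicate block without LLC library 5 and leaving out each library. Added after the data were seen were limma on log2(TPM + 1) and log2(TPM + 0.1), a threshold of 0.1, the newer deviance of edgeR, a skeletal muscle score as covariate and the joint removal of libraries that stand apart. Scores and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The days come in separate tables and no label names a batch, so day cannot be told apart from any batch of collection or library making.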

Results

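The study followed fat tissue during the growth of a transplanted lung tumour. Expression was measured in 18 libraries of inguinal fat from mice given LLC tumour cells or PBS, 7 or 21 days after injection, with 4 PBS and 5 LLC libraries at each day. Library totals lay between 14566155 and 18969387 counts, and between 15516 and 16232 genes were detected per library. Mitochondrially encoded genes took from 8.45% (day 21 LLC library 1) to 20.8% (day 21 LLC library 4) of counts.

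Several libraries stood apart from the others of their group in markers of cell types that surround fat cells. In day 21 PBS libraries 1 to 3 the macrophage score lay between -2.39 and -1.71 and the score of adipose progenitors and fibroblasts between -1.16 and -0.95. PBS library 4 of that day had 0.775 and 0.166, within the range of the day 7 libraries, and its mean rank correlation was 0.979 with the day 7 PBS libraries against 0.949 with its own group. Skeletal muscle genes were high in day 7 PBS library 3 (score 5.56) and LLC library 3 (3.16), and in day 21 PBS libraries 1 and 2 (5.49 and 3.73) and LLC libraries 2 and 5 (4.07 and 2.73). B cell and lymph node genes had a score of 5.86 in day 21 LLC library 3, against 0.916 or less elsewhere, and cell cycle genes a score of 2.85 in day 21 LLC library 1. The first principal component, 30.7% of the variance, placed day 21 PBS libraries 1 to 3 between 53.7 and 83.2 and library 4 at -15.8.

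**Figure D1:**
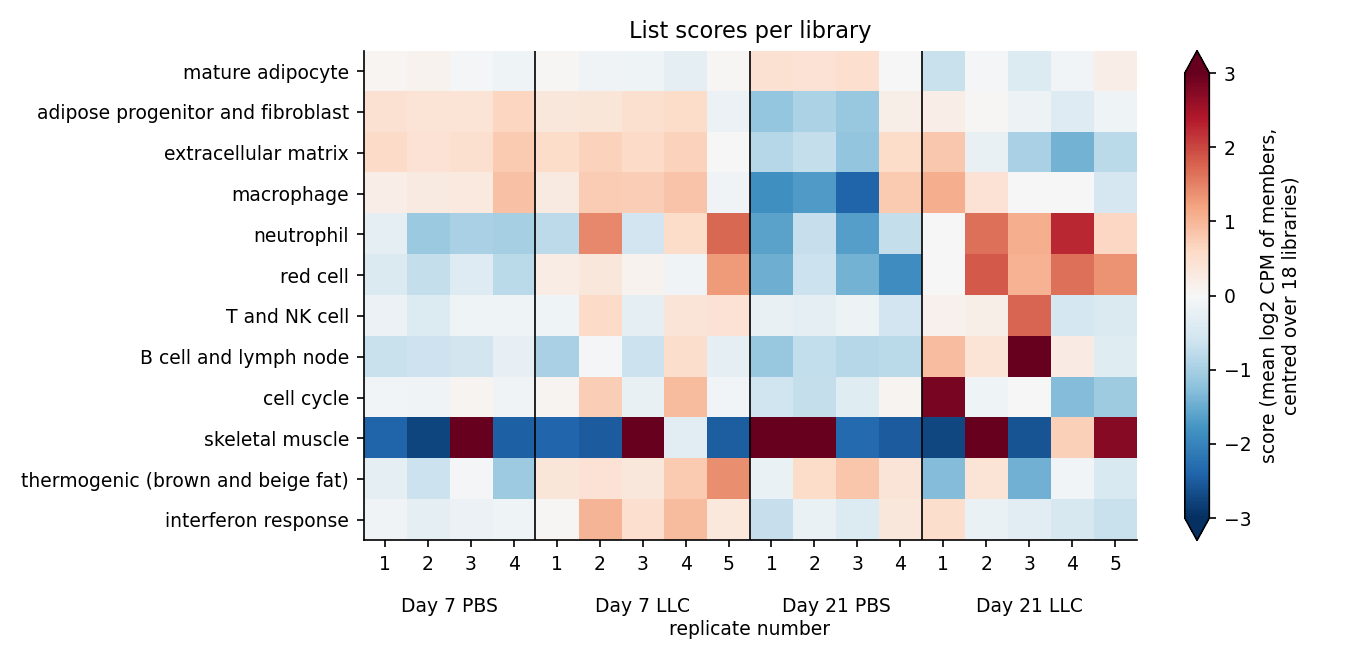
Heat map of 12 gene list scores (mean log2 CPM of the members relative to their mean over all 18 libraries; colour clipped at 3 in either direction) in each library, grouped by day and injection. Day 21 PBS libraries 1 to 3 are low for macrophage genes (-2.39 to -1.71) while library 4 is at 0.775, and the B cell score of day 21 LLC library 3 is 5.86.

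The first comparison asked which transcripts differed in fat at day 7, the stage the labels call pre-cachexia. Ucp1 (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452), which encodes the uncoupling protein through which brown and beige fat produce heat, rose from 0.708 ± 0.436 CPM in PBS (SD, n = 4) to 27.5 ± 12.1 CPM in LLC (n = 5). Its log2 fold change was 5.28 ± 0.51 (SE; edgeR adjusted p = 0.00802), and each LLC library exceeded each PBS library. Otop1 (ENSMUSG00000051596, chromosome 5, 38275972 to 38304217), which encodes a proton channel and is the gene in the series title, measured 7.58 ± 2.08 CPM in PBS and 16.7 ± 2.68 CPM in LLC. That log2 difference of 1.14 ± 0.19 did not pass over all genes in edgeR (adjusted p = 0.325; 0.176 with the paired block, fitted without LLC library 5, and 0.281 without that library alone) but did in DESeq2 (adjusted p = 4.53e-05). Tested alone, Otop1 and Ucp1 each had an exact two-sided permutation p = 0.0159, the smallest that 4 against 5 libraries allow. Exchange only within the 4 numbered pairs, added after the data were seen, gave an exact two-sided p = 0.125 for both, the smallest that 4 pairs allow. Otop1 was taken from the series title, which may itself rest on these libraries. Its p tested alone, here and at day 21, may therefore not be independent support. The fat cell hormones did not pass: Adipoq, adiponectin (ENSMUSG00000022878, chromosome 16, 23146536 to 23158028), had a log2 difference of -0.04 ± 0.10 (adjusted p = 0.951), and Lep, leptin (ENSMUSG00000059201, chromosome 6, 29060220 to 29073877), one of -0.33 ± 0.14 (adjusted p = 0.578).

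Ucp1 was the 1 gene of 13445 past the edgeR threshold at day 7, while 1144 had an unadjusted p under 0.05 and DESeq2 called 80 (62 higher, 18 lower). The genes with the smallest p below it did not pass in edgeR. On the higher side these were the interferon-induced Ifit3b (13.8 ± 1.31 against 24.6 ± 3.69 CPM; log2 0.84 ± 0.12, adjusted p = 0.2), Isg15, a ubiquitin-like protein (5.72 ± 0.834 against 17.4 ± 6.27 CPM; log2 1.61 ± 0.29, adjusted p = 0.334), and Ifi44 (log2 1.55 ± 0.28). On the lower side were the transcription factor Dmrt2 (52.5 ± 4.84 against 28.8 ± 6.36 CPM; log2 -0.87 ± 0.15, adjusted p = 0.325). After it came Ugt3a2 (-1.99 ± 0.35), the organic cation transporter Slc22a4 (-0.50 ± 0.09) and Phgdh, the first enzyme of serine synthesis (-0.46 ± 0.09), with adjusted p = 0.334 for these 3. PBS and LLC values did not overlap for 334 genes, 2.48% of those tested, where chance gives 1.59%. Ucp1 missed the threshold without PBS library 1 (adjusted p = 0.0988), 2 (0.0933) or 3 (0.053), without PBS and LLC libraries 3 together (0.144) and in 1 fit of all 18 libraries (adjusted p = 1). Without LLC library 1, Isg15 (adjusted p = 0.00283) and Ifi44 (0.00941) also passed, and without LLC library 5, Ifit3b and Dmrt2 did (0.0469 each).

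**Figure D2:**
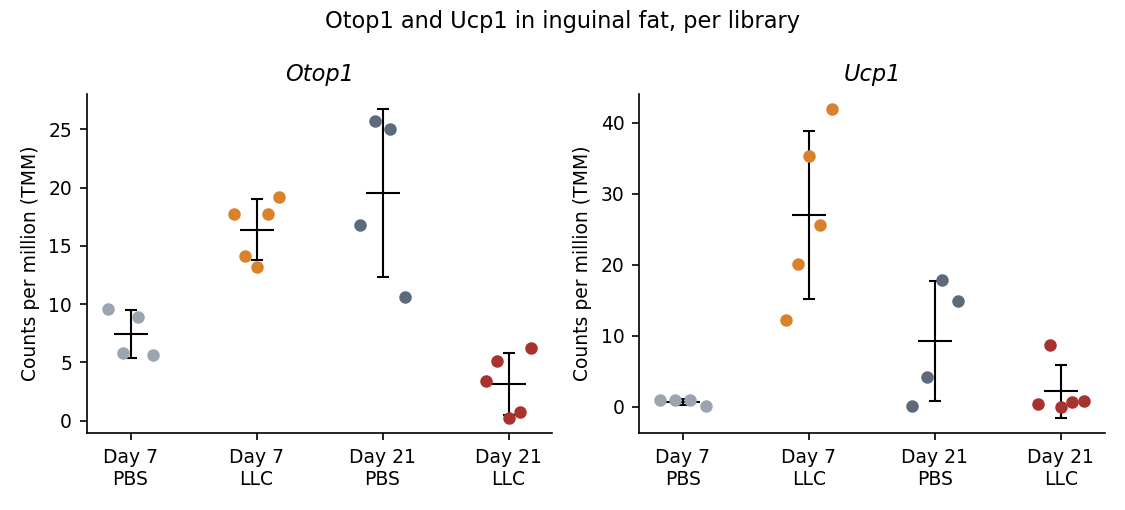
CPM of Otop1 and Ucp1 in each library (points; TMM scaling over all 18 libraries) by day and injection, with the group mean as a horizontal line and SD as error bars. Otop1 means are 7.48 and 16.4 CPM in PBS and LLC at day 7 and 19.6 and 3.14 CPM at day 21.

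Of the 27 gene lists, 15 passed camera at day 7, and 0 of them did with an estimated correlation. Thermogenic genes of brown and beige fat rose as a list: 17 of 19 measured members were higher, with a median log2 of 1.11 (camera adjusted p = 1.52e-10; adjusted p = 0.363 with an estimated correlation). Over all genes 1 member, Ucp1, rose, and adjusted over the list alone 8 rose and 1, Ebf2, fell (a gene outside the naming rule). Acot11, an acyl-CoA thioesterase, measured log2 1.64 ± 0.31 and Elovl3, a fatty acid elongase induced in brown fat, 3.39 ± 0.65. Fatty acid oxidation genes rose, with 17 of 18 higher and a median of 0.28 (adjusted p = 3.36e-05; adjusted p = 0.524 with an estimated correlation). Examples are Pdk4, a kinase that restrains glucose oxidation (0.90 ± 0.28), and Hadhb (0.46 ± 0.19). In oxidative phosphorylation, 20 of 20 were higher by a median of 0.10 (adjusted p = 0.0129; adjusted p = 0.769 with an estimated correlation), among them Cycs, cytochrome c (0.28 ± 0.09). Mature adipocyte genes fell slightly, with 16 of 20 lower, a median of -0.09 and Slc7a10 at -0.28 ± 0.12 (adjusted p = 0.0192; adjusted p = 0.589 with an estimated correlation). Cholesterol synthesis genes fell by a median of 0.17 with 16 of 20 lower, such as Mvk, mevalonate kinase, at -0.22 ± 0.10 (adjusted p = 0.0349; adjusted p = 0.735 with an estimated correlation). Progenitor and fibroblast genes fell by a median of 0.14 with 11 of 16 lower, such as Smoc2 (-0.49 ± 0.16) and Col15a1 (-0.48 ± 0.17; adjusted p = 0.0287; adjusted p = 0.58 with an estimated correlation). In the last 5 of these 6 lists edgeR put no member past the threshold, over all genes or adjusted over the list alone.

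Interferon response genes rose at day 7: 24 of 24 were higher, with a median log2 of 0.79 (camera adjusted p = 7.98e-20; adjusted p = 0.363 with an estimated correlation). No member passed over all genes, and 21 rose adjusted over the list alone, including Bst2, which tethers budding virus (0.98 ± 0.20), and Ifit1 (0.85 ± 0.18). Interferon scores were 1.02 and 0.955 in LLC libraries 2 and 4 and 0.0428 to 0.504 in the other LLC libraries, against -0.299 to -0.0997 in PBS. Red cell genes rose, 5 of 5 higher by a median of 1.06 and all 5 past the threshold adjusted over the list alone (adjusted p = 5.65e-07; adjusted p = 0.363 with an estimated correlation). Hbb-bs, adult beta globin, measured 351 ± 45.8 and 733 ± 311 CPM. T and NK cell genes rose (17 of 19 higher, median 0.36, adjusted p = 0.000153), as did endothelial genes (14 of 16, median 0.16, adjusted p = 0.00168). So did cell cycle genes (29 of 29, median 0.45, adjusted p = 1.16e-06), glucocorticoid responsive genes (15 of 17, median 0.37, adjusted p = 0.000656) and neutrophil genes (4 of 6, median 1.16, adjusted p = 0.0349). Each of these 5 lists had adjusted p = 0.524 with an estimated correlation. Cell cycle scores were 0.741 and 0.947 in LLC libraries 2 and 4 and -0.225 to 0.0883 in the other LLC libraries, against -0.0975 to 0.0724 in PBS. Acute phase genes (14 of 20, median 0.32, adjusted p = 0.00211; adjusted p = 0.399 with an estimated correlation) and immediate early genes of handling stress (14 of 15, median 0.62, adjusted p = 0.00142; adjusted p = 0.533 with an estimated correlation) also rose. Over all genes 0 members of these lists passed in edgeR. Adjusted over the list alone, 3 acute phase genes (Lrg1, Cebpb and Il1r1) and 4 neutrophil genes (Hdc, S100a9, S100a8 and Csf3r) rose and Elane, outside the naming rule, fell, with none in the other 5 lists. Single values were 1.35 ± 0.53 for Cd8a, 0.96 ± 0.39 for Gzmb, 0.27 ± 0.09 for Esam, 0.37 ± 0.11 for the replication factor Mcm6 and 1.01 ± 0.32 for the metallothionein Mt2. Others were 4.13 ± 1.14 for S100a9, 0.63 ± 0.16 for Cebpb, 2.25 ± 0.74 for Saa3 and 1.58 ± 0.57 for Egr1. None of the 9 passed over all genes in edgeR, while Cebpb did in DESeq2 (adjusted p = 0.0436). Immediate early genes had a score of 1.41 in LLC library 2 and 0.384 or less in the other 8 libraries of the day.

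The other 12 lists did not pass at day 7. Their medians and adjusted p were -0.05 and 0.866 for futile cycling outside UCP1 (where Gk rose adjusted over the list alone), -0.09 and 0.183 for lipogenesis, and 0.01 and 0.996 for lipolysis. They were 0.08 and 0.482 for mitochondrially encoded genes, -0.17 and 0.0955 for extracellular matrix, and -0.11 and 0.0901 for the circadian clock. Markers of other cells gave 0.13 and 0.349 for macrophages, 0.10 and 0.73 for B cells, 0.16 and 0.267 for epithelium and -1.93 and 0.285 for skeletal muscle, whose score was high in 1 library of each group. Autophagy genes had a positive median with a negative mean and test, and Schwann cell genes a negative median and mean with a positive test (adjusted p = 0.996 for both). With the paired block, which leaves out LLC library 5, oxidative phosphorylation (adjusted p = 0.63) and progenitor, cholesterol and neutrophil genes (0.141 each) lost their calls and macrophage genes gained one (0.000122). Leaving out LLC library 5 without a block moved the same 5 calls.

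Calls at day 7 that rested on single libraries were those of mature adipocyte genes (adjusted p without PBS library 1, 0.0837; PBS 2, 0.114; LLC 3, 0.0515; LLC 4, 0.25) and cholesterol synthesis (PBS 1, 0.0837; PBS 3, 0.942; LLC 3, 0.181; LLC 4, 0.0627; LLC 5, 0.112). Others were oxidative phosphorylation (PBS 4, 0.716; LLC 5, 0.661), progenitors (PBS 4, 0.178; LLC 5, 0.112) and neutrophils (LLC 2, 0.0962; LLC 5, 0.109). In the other direction, lists passed without single libraries: lipogenesis (PBS 2, 0.0169; PBS 4, 0.0368), mitochondrially encoded (PBS 1, 0.00801; LLC 3, 0.0176) and extracellular matrix (PBS 2, 0.0295; LLC 2, 0.0465; LLC 4, 0.0497). The same held for clock (PBS 4, 0.00752), macrophage (PBS 4, 0.0112; LLC 5, 0.001) and skeletal muscle (LLC 3, 0.0286). With the skeletal muscle score as a covariate cholesterol (0.122) and neutrophil genes (0.0555) lost their calls, and without PBS and LLC libraries 3 together the cholesterol list turned upward (0.609).

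At day 21, the stage of cachexia, genes of connective tissue mast cells were higher in LLC than in PBS. The proteases Cma1 (ENSMUSG00000022225, chromosome 14, 55941451 to 55944675), Mcpt4 (ENSMUSG00000061068, chromosome 14, 56059629 to 56062313), Tpsb2 (ENSMUSG00000033825, chromosome 17, 25366305 to 25369098) and Cpa3 (ENSMUSG00000001865, chromosome 3, 20215620 to 20242181) all rose. Cma1, mast cell chymase, went from 0.945 ± 0.403 CPM in PBS (SD, n = 4) to 16.5 ± 5.13 CPM in LLC (n = 5), a log2 fold change of 4.12 ± 0.36 (SE; edgeR adjusted p = 0.00895). Cpa3 rose by 4.53 ± 0.44 (adjusted p = 0.011), Mcpt4 by 4.44 ± 0.48 (adjusted p = 0.0167) and Tpsb2 by 4.14 ± 0.49 (adjusted p = 0.0169). On the scale of all 18 libraries Cma1 stood at 10.6 ± 3.14 CPM in PBS and 12.7 ± 4.74 CPM in LLC at day 7, so the day 21 PBS libraries, at 0.951 ± 0.405 CPM, were the low group.

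**Figure D3:**
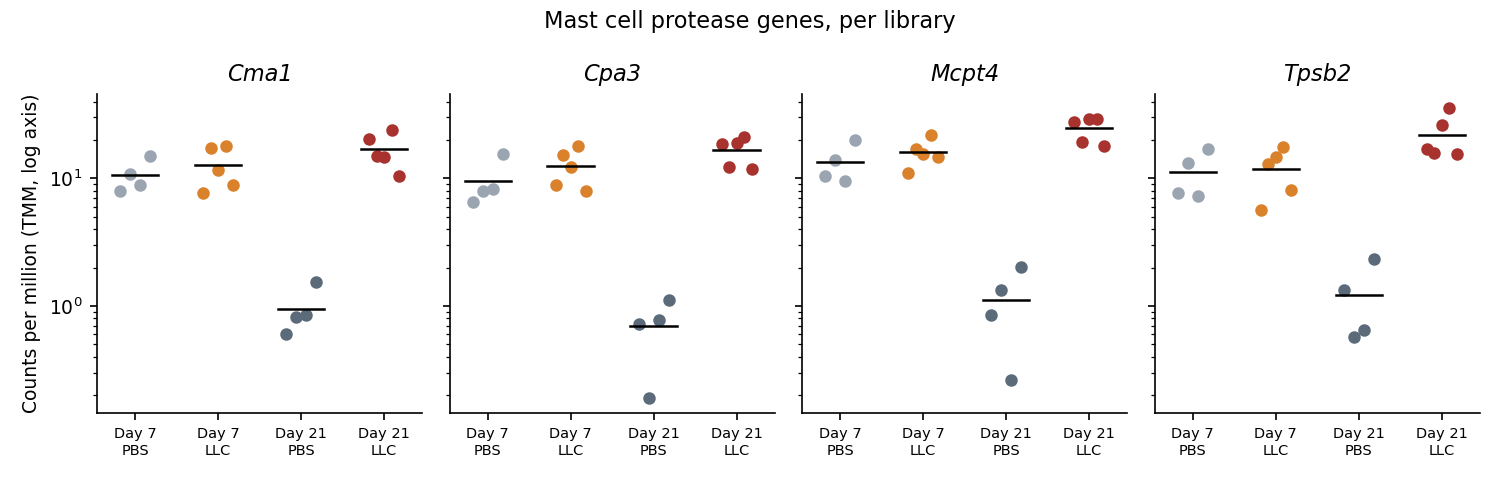
CPM (log axis; TMM scaling over all 18 libraries) of the mast cell proteases Cma1, Cpa3, Mcpt4 and Tpsb2 in each library (points) by day and injection, with the group mean as a horizontal line. Day 21 PBS means are 0.951, 0.700, 1.11 and 1.22 CPM, and day 21 LLC means are 16.9, 16.6, 24.7 and 22 CPM.

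Otop1 measured 19.4 ± 7.16 CPM in PBS and 3.07 ± 2.58 CPM in LLC at day 21 (SD, n = 4 and 5), a log2 difference of -2.66 ± 0.74 that did not pass over all genes in edgeR (adjusted p = 0.099). It passed in DESeq2 (adjusted p = 0.00632) and in 1 fit of all 18 libraries (0.00602), and every LLC library lay below every PBS library (exact two-sided permutation p = 0.0159). Ucp1 measured 9.20 ± 8.41 CPM in PBS and 2.07 ± 3.61 CPM in LLC (exact permutation p = 0.159), with PBS libraries from 0.12 to 17.7 CPM. Adipoq had a log2 difference of -0.20 ± 0.28 (adjusted p = 0.686) and Lep one of -1.15 ± 0.50 (adjusted p = 0.203). Past the threshold, Mmrn1, multimerin of platelets and lymphatic endothelium, rose from 0.0942 ± 0.0629 to 5.39 ± 2.72 CPM (log2 5.74 ± 0.66, adjusted p = 0.0169). Selp, the adhesion molecule P-selectin, rose by 2.85 ± 0.41 and Alas2, the heme synthesis enzyme of red cell precursors, by 2.78 ± 0.39 (adjusted p = 0.0489 for both). The guidance molecule Sema3f rose by 1.47 ± 0.20 (adjusted p = 0.0443) and Id2, an inhibitor of basic helix-loop-helix factors, by 0.96 ± 0.11 (adjusted p = 0.0169). The histone gene H2bc4 fell from 86.7 ± 3.04 to 46.9 ± 4.67 CPM (log2 -0.89 ± 0.10, adjusted p = 0.0167). Trim67 fell by 1.29 ± 0.17 (adjusted p = 0.036) and the vesicular polyamine transporter Slc18b1 by 0.85 ± 0.12 (adjusted p = 0.0489). Selp, Alas2 and Slc18b1 missed the threshold with DESeq2 size factors (adjusted p = 0.0505 each), with a filter at a mean of 1 CPM (0.0539, 0.0539 and 0.0521) and in the robust fit (0.0534, 0.0534 and 0.0501), and Slc18b1 also without a filter (0.0507). With limma on log2(TPM + 1), H2bc4 (adjusted p = 0.125), Trim67 (0.111), Slc18b1 (0.0905) and Id2 (0.0584) missed it. On log2(TPM + 0.1) the first 3 did (0.119, 0.132 and 0.086). Next on the lower side and not past the threshold were Angpt1, a ligand of the endothelial receptor Tie2 (-1.07 ± 0.16), and Ppp2r5b (-1.15 ± 0.18), both with adjusted p = 0.0526.

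These 12 genes (9 higher, 3 lower) were all that passed edgeR among 13564 at day 21, with 3164 at an unadjusted p under 0.05, 763 at an adjusted p under 0.1 and 1555 in DESeq2. PBS and LLC values did not overlap for 1296 genes, 9.56% of those tested, where chance gives 1.59%. The count was 0 without PBS library 1, 2 without PBS library 2 or 3, 1277 without PBS library 4, 24, 95, 5 and 6 without LLC libraries 1, 2, 3 and 4, and 962 without PBS library 4 and LLC libraries 1 and 3 together. It was 2660 in 1 fit of all 18 libraries, which shares the smaller spread of day 7.

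Of the 27 lists, 19 passed camera at day 21, and 0 of them did with an estimated correlation. Most lists of fat cell function were lower in LLC than in PBS, and over all genes 0 of their members passed in edgeR. For some of these lists the medians rose within PBS between the days and hardly moved within LLC, as given below. Lipogenesis genes fell by a median log2 of 1.03 with 22 of 23 lower (camera adjusted p = 7.36e-07) and 2 past the threshold adjusted over the list alone, Pnpla3 (-1.79 ± 0.36) and Scd2 (-1.82 ± 0.45). Dgat2, which completes triglyceride synthesis, measured -1.54 ± 0.50. Cholesterol synthesis genes fell by 0.90 with 17 of 20 lower (adjusted p = 5.11e-06), 11 of them adjusted over the list alone, among them Hmgcs1 (-1.20 ± 0.21), Mvk (-0.80 ± 0.15) and Lss (-1.27 ± 0.26). Lipolysis genes fell by 0.65 with 16 of 19 lower (adjusted p = 0.000159) and 8 adjusted over the list alone, such as Prkaca, a catalytic subunit of protein kinase A (-0.89 ± 0.17), Mgll (-0.83 ± 0.22) and the adrenergic receptor gene Adrb1 (-2.42 ± 0.67). Thermogenic genes fell by 0.69 with 17 of 19 lower (adjusted p = 0.00104). In that list 7 fell adjusted over the list alone, such as Cox7a1 (-2.21 ± 0.60) and Cpt1b (-2.34 ± 0.68), and 2 rose, Tbx1 (1.80 ± 0.48) and Tmem26. Mature adipocyte genes fell by 0.45 with 17 of 20 lower (adjusted p = 6.73e-05) and 1 adjusted over the list alone, the lipid droplet coat gene Plin1 (-0.96 ± 0.21). Lpl measured -0.95 ± 0.34. Fatty acid oxidation genes fell by 0.62 with 17 of 18 lower (adjusted p = 2.61e-05), 3 of them adjusted over the list alone: Acaa2 (-0.95 ± 0.21), Cpt2 (-0.82 ± 0.20) and Cpt1b. Futile cycling genes fell by 0.43 with 8 of 10 lower (adjusted p = 0.0393) and 2 adjusted over the list alone, Pm20d1 (-1.64 ± 0.34) and Gamt (-1.06 ± 0.30). For each of these 7 lists the test gave adjusted p = 0.456 with an estimated correlation. Oxidative phosphorylation genes fell by 0.46 with 20 of 20 lower, such as Uqcrc1 at -0.70 ± 0.21 (adjusted p = 6.73e-05; adjusted p = 0.572 with an estimated correlation). Mitochondrially encoded genes fell by 0.27 with 11 of 13 lower, such as mt-Nd2 at -0.60 ± 0.36 (adjusted p = 0.035; adjusted p = 0.732 with an estimated correlation). Neither list had a member past the threshold adjusted over the list alone. Beside these falls, day 21 PBS libraries 1 to 3 had mature adipocyte scores of 0.427 to 0.502 and library 4 one of -0.016, while LLC libraries 1 and 3, with the low scores of -0.675 and -0.409, were those with high cell cycle and B cell scores. From day 7 to day 21 the medians were 0.43 in PBS and 0.001 in LLC for mature adipocyte genes. They were 0.51 and 0.01 for oxidative phosphorylation, 0.52 and -0.08 for lipolysis and 0.42 and 0.05 for mitochondrially encoded genes. For lipogenesis they were 0.41 and -0.46, for thermogenic genes 0.81 and -0.62 and for fatty acid oxidation 0.63 and -0.25. Cholesterol synthesis had -0.07 and -0.79, and futile cycling 0.10 and -0.30.

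Lists of several immune and vascular cells passed at day 21. Macrophage genes were higher for 20 of 20 members by a median of 0.93 (camera adjusted p = 8.01e-06) with none past the threshold adjusted over the list alone; Ccr2, a monocyte chemokine receptor, measured 1.33 ± 0.36 and Cd163 1.53 ± 0.47. The macrophage scores of PBS libraries 1 to 3 were the lowest of all 18 libraries, and that of PBS library 4, at 0.775, exceeded 4 of the 5 LLC libraries. Neutrophil genes were higher for 7 of 7 by a median of 2.39 (adjusted p = 2.84e-05), and 5 rose adjusted over the list alone: Mmp9 (1.47 ± 0.23), Hdc (2.39 ± 0.38), S100a9 (4.56 ± 1.05), Cxcr2 (5.20 ± 1.28) and S100a8. Cxcr2 was near the floor in PBS (log2(CPM + 1) of 0.395 or less), so its fold change is uncertain. LLC library 4, high for Hdc, had the highest neutrophil and mast cell scores alike (2.26 and 1.57), so Hdc does not tell these cells apart here. B cell and lymph node genes were higher for 11 of 11 by a median of 5.25 (adjusted p = 0.000863), with 10 adjusted over the list alone, such as Jchain (3.15 ± 0.70) and Igkc (4.80 ± 1.28). Without PBS library 4 and LLC libraries 1 and 3 Jchain measured 1.89 and Igkc 1.44. LLC library 3 had a score of 5.86 and the other LLC libraries -0.367 to 0.916. Endothelial genes were higher for 13 of 16 by a median of 0.51 (adjusted p = 0.000261) and 9 rose adjusted over the list alone, such as Vwf (2.39 ± 0.41), Tek (0.89 ± 0.17) and Pecam1 (1.06 ± 0.22). Red cell genes were higher for 5 of 5 by a median of 2.51 (adjusted p = 1.49e-06): Alas2 rose over all genes and all 5 adjusted over the list alone, with Hbb-bs at 203 ± 82.2 and 1250 ± 494 CPM. Schwann cell genes fell by 0.85 with 10 of 11 lower (adjusted p = 6.73e-05) and 6 adjusted over the list alone, such as the myelin gene Mag (-1.34 ± 0.31). All 6 lists had adjusted p = 0.456 with an estimated correlation.

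Signalling and growth lists passed by less at day 21. Glucocorticoid responsive genes rose by a median of 0.73 with 13 of 17 higher (camera adjusted p = 0.0092; adjusted p = 0.572 with an estimated correlation), and adjusted over the list alone Mt2 (2.59 ± 0.59), Nfkbia (0.86 ± 0.24) and Mt1 rose. Acute phase and IL-6 family genes rose by 0.71 with 14 of 20 higher (adjusted p = 0.035; adjusted p = 0.582 with an estimated correlation). Adjusted over the list alone 5 of them rose, including Osmr, the oncostatin M receptor (0.95 ± 0.15), Socs3 (1.68 ± 0.34) and Stat3 (0.65 ± 0.14), while Orm1, an acute phase glycoprotein, fell (-2.32 ± 0.42). Progenitor and fibroblast genes rose by 0.62 with 11 of 16 higher (adjusted p = 0.035; adjusted p = 0.572 with an estimated correlation), and the 1 member past the threshold adjusted over the list alone was Has1, a hyaluronan synthase (3.29 ± 0.56). Cell cycle genes rose by 1.56 with 29 of 29 higher (adjusted p = 0.035; adjusted p = 0.785 with an estimated correlation), and adjusted over the list alone Mcm7 did (0.82 ± 0.19). LLC library 1 had a score of 2.85 and the other 4 LLC libraries -1.31 to -0.0174.

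The remaining 8 lists did not pass at day 21. Interferon response genes had 12 members higher and 12 lower (adjusted p = 0.476), and Cxcl9 alone fell adjusted over the list alone (-1.23 ± 0.24). Adjusted p was 0.816 for extracellular matrix and for autophagy (median 0.07), 0.265 for the circadian clock (median -0.40; Npas2 at 3.61 ± 0.97), 0.425 for immediate early genes, 0.141 for T and NK cells (median 0.81), 0.413 for skeletal muscle (median -1.53) and 0.91 for epithelium. Median and test had opposite signs for epithelium (0.78, tested downward with a positive mean) and immediate early genes (-0.03, tested upward with a positive mean), and extracellular matrix (-0.26) and interferon genes (-0.02) had positive means with downward tests.

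Leaving out 1 library ended calls at day 21 for futile cycling (adjusted p without PBS library 4, 0.0626; LLC 3, 0.0832; LLC 4, 0.0728) and mitochondrially encoded genes (PBS 2, 0.0741; PBS 3, 0.115; PBS 4, 0.0589; LLC 1, 0.202; LLC 3, 0.174). The same held for acute phase (PBS 1, 0.0678; PBS 3, 0.136; PBS 4, 0.0509; LLC 1, 0.135; LLC 2, 0.118) and progenitors (PBS 1, 0.0523; PBS 2, 0.0572; PBS 3, 0.0752; LLC 1, 0.186; LLC 2, 0.1; LLC 5, 0.0601). Cell cycle lost its call too (PBS 1, 0.0551; PBS 2, 0.0727; PBS 4, 0.0504; LLC 3, 0.0543), and without LLC 1 the cell cycle list tested downward (0.415). Other lists passed when 1 library was left out: extracellular matrix (LLC 1, 0.0134), interferon (LLC 1, 0.0395), immediate early (PBS 2, 0.000967), T and NK cells (LLC 4, 0.0221) and skeletal muscle (PBS 3, 0.0368). With the skeletal muscle score as a covariate, mitochondrially encoded (0.0535), acute phase (0.0535) and cell cycle genes (0.054) lost their calls.

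**Figure D4:**
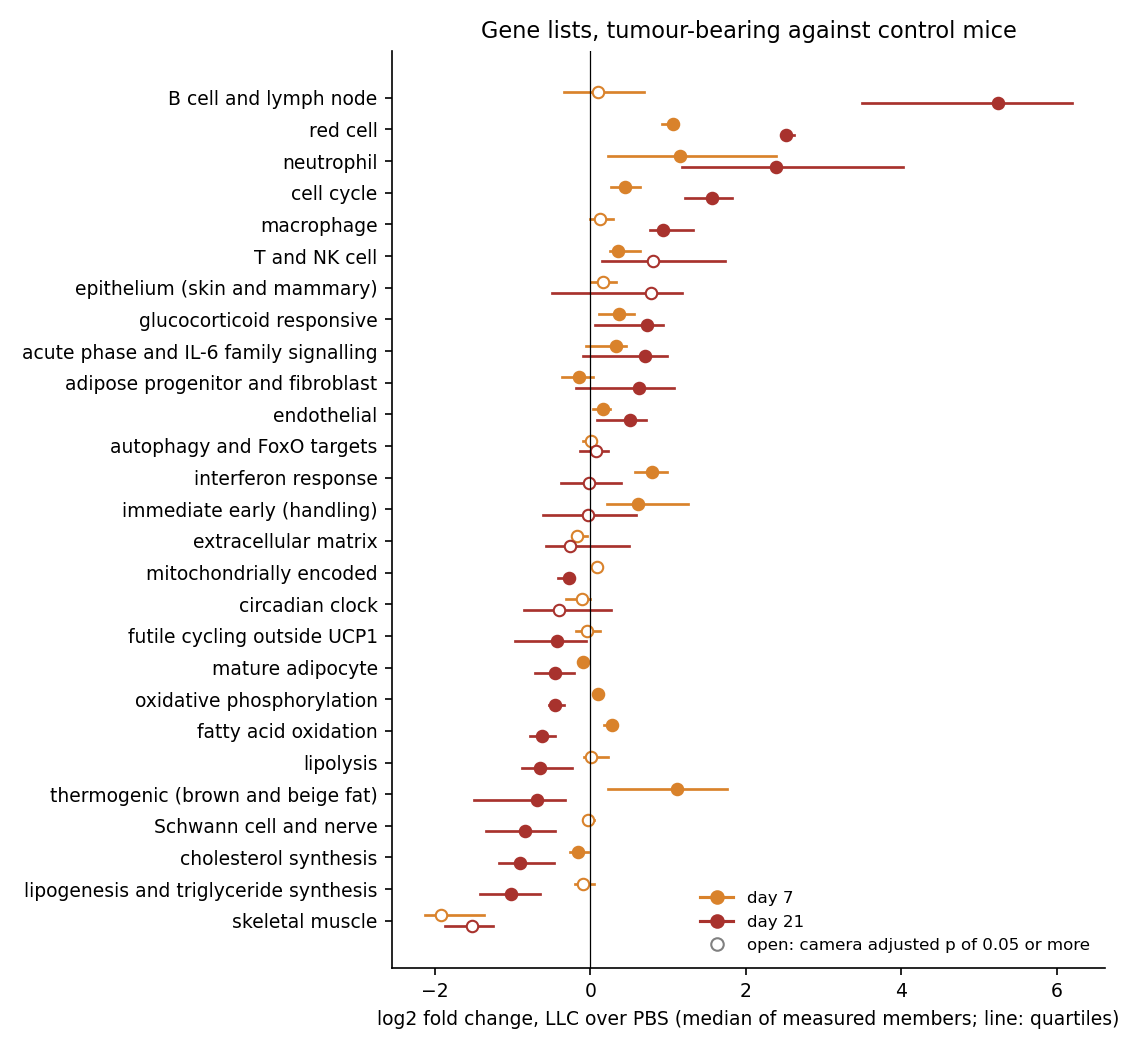
Median log2 fold change (LLC over PBS) of the measured members of the 27 gene lists at day 7 (orange) and day 21 (red), with lines from the lower to the upper quartile; filled points passed camera with the preset correlation and open points did not. Thermogenic genes have medians of 1.11 at day 7 and -0.69 at day 21, and interferon response genes 0.79 and -0.02.

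The next test asked for which genes the tumour effect itself differed between day 7 and day 21. Otop1 was such a gene: its effect went from higher to lower, a log2 difference of -3.78 ± 0.79 (SE; edgeR adjusted p = 0.044). Its means were 7.48 ± 2.06 and 16.4 ± 2.60 CPM (PBS and LLC, day 7) and 19.6 ± 7.20 and 3.14 ± 2.63 CPM (day 21; SD, n = 4 and 5 at each day). The difference for Ucp1 was -7.40 and did not pass (adjusted p = 0.0571). Mast cell proteases had the smallest p on the higher side: Mcpt4 (4.20 ± 0.50) and Cma1 (3.88 ± 0.46), both with adjusted p = 0.00151. Next were Cpa3 (4.16 ± 0.52, adjusted p = 0.00177) and Tpsb2 (4.09 ± 0.61, adjusted p = 0.00927), followed by Id2 (0.97 ± 0.14, adjusted p = 0.00927). On the lower side were H2bc4 (-0.94 ± 0.13, adjusted p = 0.00505), the cochaperone Dnaja4 (-0.99 ± 0.16), Slc18b1 (-0.88 ± 0.15), the laminin subunit Lamc3 (-1.83 ± 0.33) and Mecr, of mitochondrial fatty acid synthesis (-1.13 ± 0.20). With the replicate block, fitted without LLC library 5 of each day, H2bc4 (adjusted p = 0.0538), Dnaja4 (0.0598), Slc18b1 (0.0636) and Mecr (0.0552) missed the threshold. With limma on log2(TPM + 1) all 5 and Id2 (0.062) missed it: H2bc4 (adjusted p = 0.164), Dnaja4 (0.0909), Slc18b1 (0.164), Lamc3 (0.062) and Mecr (0.0581). The same 6 missed it on log2(TPM + 0.1). Leaving out 1 library ended the call for Lamc3 in 9 of 18 cases (adjusted p from 0.0508 to 0.0811) and for Mecr in 10 (0.0508 to 0.0892). It did so for Slc18b1 in 5 (0.0543 to 0.0721) and for Dnaja4 in 2 (0.0548 and 0.0505).

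In all 58 of 13975 genes differed between days in edgeR (37 higher, 21 lower at day 21), 722 in DESeq2. By list, 17 of 27 passed camera, again none with an estimated correlation. The effect on thermogenic genes was lower at day 21 by a median of 1.91 log2 units in 17 of 19 members (adjusted p = 4.06e-08; adjusted p = 0.373 with an estimated correlation). Over all genes Otop1 and Acot11 (-3.39) fell, and adjusted over the list alone 11 fell and 1, Tmem26, rose. From day 7 to day 21 thermogenic genes rose within PBS by a median of 0.81, 17 of 19 higher (camera adjusted p = 0.00159, and 0.566 with an estimated correlation). Within LLC they fell by 0.62, 17 of 19 lower (camera adjusted p = 1.25e-06, and 0.381 with an estimated correlation). The lower effect at day 21 thus held a rise in PBS as well as a fall in LLC. For fatty acid oxidation the effect was lower by 0.88 in 17 of 18 (adjusted p = 3.24e-08; adjusted p = 0.373 with an estimated correlation), 14 of them adjusted over the list alone. For interferon response it was lower by 0.79 in 22 of 24 (adjusted p = 6.14e-07; adjusted p = 0.433 with an estimated correlation), with Cxcl9 (-1.48) past the threshold over all genes and 9 adjusted over the list alone. Endothelial genes had a higher effect by a median of 0.31 in 12 of 16 (adjusted p = 0.00949; adjusted p = 0.481 with an estimated correlation), with Vwf (2.10) and Tek (0.99) past the threshold over all genes and 5 adjusted over the list alone. Otop1 missed the threshold when any 1 day 7 library, day 21 PBS library 1, 2 or 3, or day 21 LLC library 4 was left out (adjusted p from 0.0517 to 0.125), with values from -3.92 to -3.53. It also missed it with the replicate block fitted without LLC library 5 of each day (0.0536; 0.0739 without that of day 7 alone) and with limma on log2(TPM + 0.1) (0.056). The count of 58 was 6 to 20 with any 1 of the day 7 libraries other than LLC 4 or day 21 PBS libraries 1 to 3 left out and 1222 without day 21 PBS library 4. It was 167, 369 and 105 without day 21 LLC libraries 1, 2 and 5, and 35 without LLC library 3.

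Day 21 was also compared with day 7 within PBS, the background of age, day of collection and batch. Mast cell proteases fell, with values of -3.47 ± 0.37 for Cma1, -3.75 ± 0.42 for Cpa3 and -3.58 ± 0.40 for Mcpt4. The macrophage lectin Mgl2 (-1.66 ± 0.19) and the protocadherin Pcdh18 (-1.7 ± 0.19) fell too (log2 ± SE, n = 4 and 4, edgeR adjusted p = 0.000292 for all 5). Slc5a6, a vitamin transporter (1.16 ± 0.23, adjusted p = 0.0169), and Pigr, the polymeric immunoglobulin receptor of epithelia (3.29 ± 0.68, adjusted p = 0.021), rose, as did Pcgf5 (0.65 ± 0.13), Actr1b (0.40 ± 0.08) and Tmco4 (0.49 ± 0.10). All 5 of these risers missed the threshold in both limma fits on log2 TPM (adjusted p from 0.0617 to 0.4). They also missed it without day 7 PBS library 2 or 4 or day 21 PBS library 2 (adjusted p from 0.0506 to 0.0902). Otop1 measured 1.39 ± 0.57 (adjusted p = 0.183), and 1.6 (adjusted p = 0.0108) without day 21 PBS library 4 and LLC libraries 1 and 3. Macrophage genes fell by a median of 1.01 in 19 of 20 members (camera adjusted p = 8.24e-09; adjusted p = 0.566 with an estimated correlation), with Cd163 and Ccr2 past the threshold over all genes and 3 adjusted over the list alone. Progenitor and fibroblast genes fell by 0.93 in 15 of 16 (adjusted p = 1.72e-07, and 0.566 with an estimated correlation), 4 of them over all genes and 7 adjusted over the list alone. Day 21 PBS libraries 1 to 3 carried most of both falls, with macrophage scores of -2.39 to -1.71 and progenitor scores of -1.16 to -0.951. Library 4 had scores of 0.775 and 0.166. Fatty acid oxidation genes rose by 0.63 in 17 of 18 (adjusted p = 1.08e-06; adjusted p = 0.566 with an estimated correlation), 3 adjusted over the list alone. In edgeR 449 genes passed (97 higher, 352 lower), and 1109 in DESeq2. With limma 15 were higher and 404 lower on log2(TPM + 1), and 10 and 469 on log2(TPM + 0.1). No gene was higher, and 81, 65 and 41 were lower, without day 7 PBS library 2, day 7 PBS library 4 or day 21 PBS library 2. Without day 21 PBS library 4 the count was 1692, and it was 93, 41 and 83 without PBS libraries 1, 2 and 3 of that day. It was 156, 81, 183 and 65 without day 7 PBS libraries 1 to 4, and 263 and 286 without day 7 LLC libraries 1 and 2; it was 789 without day 21 LLC library 1.

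Within LLC, day 21 against day 7 follows the course of the tumour together with the same background. Otop1 fell by 2.39 ± 0.54 (log2 ± SE, n = 5 and 5; edgeR adjusted p = 0.0399). Trim67 fell by 1.62 ± 0.17 (adjusted p = 0.000613), as did the collagen regulator Creb3l1 (-1.63 ± 0.23, adjusted p = 0.0114), Dnaja4 (-0.71 ± 0.10), H2bc4 (-0.57 ± 0.09) and the mitochondrial carrier Slc25a35 (-1.05 ± 0.16). The water channel Aqp1 rose by 0.85 ± 0.14 (adjusted p = 0.0183), as did Unc93a2 (2.8 ± 0.47), Rif1 (0.58 ± 0.10), Ctla2a (1.28 ± 0.22) and Impdh2, of guanine nucleotide synthesis (0.70 ± 0.12). With limma on log2(TPM + 1), Aqp1 (adjusted p = 0.0532), Rif1 (0.283), Impdh2 (0.112) and H2bc4 (0.104) missed the threshold, as they did on log2(TPM + 0.1). Rif1, Ctla2a and Impdh2 missed it without day 7 LLC library 1 (adjusted p = 0.0599 each), and Unc93a2 (0.0535) and Impdh2 (0.0549) without day 7 LLC library 2. Interferon response genes fell by a median of 0.83 in 24 of 24 (camera adjusted p = 3.47e-13; adjusted p = 0.27 with an estimated correlation), with Cxcl9, Gbp3 and Gbp2 past the threshold over all genes and 16 adjusted over the list alone. Cholesterol synthesis genes fell by 0.79 in 19 of 20 (adjusted p = 3.86e-12; adjusted p = 0.27 with an estimated correlation), with Hmgcs1, Dhcr7, Mvk, Sc5d and Idi1 past the threshold over all genes and 14 adjusted over the list alone. List members named here and for PBS without values were picked after their values were seen. In edgeR 248 genes passed (118 higher, 130 lower), and 813 in DESeq2. With limma 4 were higher and 23 lower on log2(TPM + 1), and 4 and 20 on log2(TPM + 0.1). Otop1 missed the threshold without any 1 of the day 7 libraries, day 21 PBS library 2 or day 21 LLC library 4 (adjusted p from 0.0517 to 0.0954). The count was 1036 and 602 without day 21 LLC libraries 1 and 2 and 94 and 74 without LLC 3 and 4. It was 20, 15, 52 and 72 without day 7 LLC libraries 1 to 4 and 103, 84, 114 and 113 without day 7 PBS libraries 1 to 4. Leaving out single day 21 PBS libraries gave 152 and 110, for 1 and 2.

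Across 13270 genes tested at both days, the tumour effects at day 7 and day 21 correlated with Pearson's r of 0.29 and Spearman's rho of 0.249 (jackknife SE over libraries 0.189; genes are not independent replicates, and the days share no library). No gene passed at both days, where 0.000678 shared rises were to be expected from the 1 rise at day 7 and the 9 at day 21. The authors' deposited table gives 46 genes with an FDR under 0.05 at day 7 (45 higher, 1 lower) and 1159 at day 21 (872 higher, 287 lower). For Otop1 the authors' deposited table gives a log2 ratio of 1.13 at day 7 (FDR 1.54e-06) and -2.46 at day 21 (FDR 0.0089), and for Ucp1 5.29 (FDR 1.61e-15) and -2.03 (FDR 0.486).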

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

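Tests chosen only after the data were seen were those of Otop1 with the skeletal muscle covariate and relative to the mature adipocyte score, those of the mast cell list (with the progenitor covariate) and of the epithelium score, and those of the T and NK cell, B cell, cell cycle and tumour cell candidate scores in day 21 LLC libraries 1 and 3. The other splits, the search for libraries far from their group and the test of the difference between days were set beforehand.

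The first pattern is Otop1, whose tumour effect differed between days by a log2 value of -3.78, tested as an interaction in edgeR. Skeletal muscle in some libraries is argued against by its balance between the arms. The muscle score differed between LLC and PBS by -0.391 at day 7 and -0.659 at day 21, within its spread among libraries. With that score as a covariate the Otop1 difference was -3.86 ± 0.762 (SE). So balanced a score could hardly have changed it, so this fit adds little. A lower share of fat cells in general at day 21 could not be decided by the test made. The mature adipocyte score differed between LLC and PBS by -0.535, and Otop1 log2(CPM + 1) by -2.56, a larger fall. Otop1 minus that score therefore had to stay lower in LLC. It differed by -2.01 (exact two-sided permutation p = 0.0159, n = 4 and 5), which adds nothing to those values. The score need not move in step with the share of fat cells, so no conclusion on that share is drawn. The list does not separate thermogenic fat cells from others, so a lower share of those was not tested. What also stays open is a response of the tissue to the growing tumour, as the design would have it, or a difference between the days in collection or library making. The latter may act on either arm and was not tested. Chance stays open too, since 5 of 100 splits called at least 58 genes for the difference between days. The Otop1 call for that difference was also lost when any single day 7 library was left out. Within PBS, Otop1 differed between the days by a log2 value of 1.39 (adjusted p = 0.183), and by 1.6 (adjusted p = 0.0108) without day 21 PBS library 4, LLC library 1 and LLC library 3.

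The second pattern is the mast cell genes, 11 of 11 higher in LLC than in PBS at day 21 with a median log2 of 3.42 (quartiles 2.44 and 4.13). A different share of connective tissue is argued against as the whole cause: with the progenitor and fibroblast score as a covariate the median was 2.91, with a lower quartile of 2.45 and a range of 2.94 to 5.15 when 1 library was left out. That covariate ended the single-gene calls, since 0 genes of any kind passed in the fit with it. Skin or epithelium carried into the samples was judged by the epithelium score, which differed by 0.2 (0.054 to 0.415 with 1 library left out; exact two-sided permutation p = 0.571, n = 4 and 5). Such a p does not exclude a difference. The 8 measured members moved both ways, 5 higher and 3 lower with a median log2 of 0.78. The score thus argues against a shared rise of these genes, not against every kind of epithelium. What also stays open is a loss of mast cells or their transcripts in day 21 PBS fat. There the scores were -2.07 to -1.27, against -0.41 or more in all other libraries. A difference in where the depot was sampled, which may vary by group, was not tested and stays open too, as does an effect of the tumour.

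The third pattern is day 21 LLC libraries 3 and 1, which stood apart from the other LLC libraries in lists of cell types. For library 3, lymph node tissue in the sample is a candidate explanation that its T and NK cell score goes with, 1.15 above the highest of the other 17 libraries, beside a B cell score 4.95 above. For library 1, lymphoid tissue stays open, with a T and NK cell score that differed by -0.05 and a B cell score that differed by 0.51 from the highest of the day 21 LLC libraries other than 3. It cannot be told apart from tumour cells or other dividing cells in library 1: the score of tumour cell candidates lay 3.18 and the cell cycle score 1.9 above the highest other library, but the candidate genes were chosen from that library. No biological explanation was tested, since the design names none for single libraries.

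Other splits of the libraries were counted for each result of a model, the real split included. At day 7, 6 of 100 splits called at least 1 gene, the highest other split 199 (PBS library 4 and LLC libraries 2, 3 and 4 against the rest), so chance cannot be excluded. Among the 12 splits that part 4 of the numbered pairs as the real one does, 2 had a gene and the highest other had 1, while the larger counts came from splits that part fewer pairs, a structure of the samples in which PBS library 4 goes with LLC libraries 2, 3 and 4. At day 21, 3 of 100 splits reached 12 genes. That makes chance less likely but does not exclude it, since several such counts were made without correction. The highest other split called 437 and set PBS library 4 with LLC libraries 1, 2 and 3 against the rest, a structure of the samples that the groups do not explain. For the difference between days 5 of 100 reached 58, so chance cannot be excluded, and the highest other split called 1851 with the same 4 day 21 libraries together. These splits ignored the numbered pairs. Each other split that reached 58 kept at least 1 day 7 pair together, but so do most splits. Of the 100 splits counted at day 7 only 12 parted all 4 pairs, so the larger counts cannot be put down to the pairs. For day 21 against day 7, 1 of 35 splits in PBS reached 449 (highest other 0) and 2 of 100 in LLC reached 248. Chance is less likely for both, again without correction for the number of counts made. The larger LLC split, with 522, exchanged day 7 LLC library 5 with day 21 LLC library 1, which points to those libraries as a structure of the samples. For the lists passing camera, 16 of 100 splits reached 15 at day 7 (highest other 19, and 15 among those parting the pairs), where chance cannot be excluded. At day 21, 3 of 100 reached 19. The highest other split tied with the real one at 19, so chance is less likely there but not excluded.

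Libraries far from the others of their group were sought in 560 groups of 4 or 5 libraries, as the gap to the nearest library over the range of the group. Chance passes Dixon's 95% critical value in about 1 in 20 groups, 28 here, and 56 passed: 13 scores of lists and 43 of named genes. Day 21 PBS library 4 accounted for 17 of them. Whether it carries a wrong label or came from another part of the depot was not tested, and without it the day 21 count was 1277 genes in place of 12. Its mast cell (-1.27) and red cell (-1.85) scores lay below those of every library of the other groups. Its macrophage score and rank correlation lay with day 7, so its values do not settle the label. Its score was low for mature adipocytes (ratio 0.855) and high for progenitors (0.845), and among genes it was low for Ppp2r5b (0.881), Mecr (0.909), Slc5a6 (0.853), Plin1 (0.876), Cox7a1 (0.951), Scd2 (0.945), Prkaca (0.875), Uqcrc1 (0.899) and Igkc (0.96), and high for Id2 (0.832), Bst2 (0.86), Mcm6 (0.865), Ccr2 (0.89), Vwf (0.83) and Cd163 (0.849). Day 7 LLC library 5 was high for the fatty acid oxidation (0.736) and epithelium (0.728) scores, Alas2 (0.838), Sema3f (0.858), Tmco4 (0.768), Impdh2 (0.811), Cycs (0.817) and Pecam1 (0.757), and low for the extracellular matrix (0.792) and progenitor (0.721) scores. Day 7 PBS library 3 was high for the autophagy (0.865), cell cycle (0.943) and skeletal muscle (0.957) scores and low for Rif1 (0.881), and LLC library 3 of that day high for autophagy (0.763). Day 7 PBS library 4 was high for the macrophage score (0.879) and Creb3l1 (0.848) and low for Ucp1 (0.889), Adipoq (0.918) and Slc7a10 (0.842).

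The remaining ratios at day 7 were 0.851 for the neutrophil score (PBS library 1, high), 0.905 for Phgdh (PBS 2, high), 0.953 for Lrg1 (PBS 2, low) and 0.717 for Adipoq (LLC 4, low). At day 21 LLC library 1 was high for Bst2 (0.76), Mcm6 (0.759), Tpx2 (0.726) and Socs3 (0.745) and low for Dmrt2 (0.78), LLC library 3 high for the B cell score (0.794), Cd8a (0.768) and Cd2 (0.735), LLC library 2 high for Ucp1 (0.741), and LLC library 4 high for Hdc (0.784) and low for Mag (0.73). PBS library 1 was low for Mmrn1 (0.946), PBS library 2 high for Egr1 (0.853) and Cxcr2 (0.978), and PBS library 3 high for Cd8a (0.891).

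Beside Otop1, the tumour effect differed between days past the edgeR threshold, as day 21 minus day 7 in log2 units, for Mmrn1 (5.53), Mcpt4 (4.20), Cpa3 (4.16), Tpsb2 (4.09), Cma1 (3.88), Vwf (2.10), Mgl2 (1.22), Tek (0.99) and Id2 (0.97), and in the other direction for Acot11 (-3.39), Lamc3 (-1.83), Cxcl9 (-1.48), Slc25a35 (-1.28), Mecr (-1.13), Dnaja4 (-0.99), H2bc4 (-0.94) and Slc18b1 (-0.88).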

How the results depend on the processing

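Chosen only after the data were seen were the tests with a threshold of 0.1, the newer deviance of edgeR, limma on TPM, the skeletal muscle covariate, the joint removal of libraries and the exact permutation of list scores; the others were set beforehand. Limma on FPKM was not run, since the tables give TPM, which was used instead. For changed counts the cause was not tested unless given. Depth was alike in all libraries, but the spread at day 21 limits what edgeR calls there. The biological coefficient of variation was 0.379, against 0.173 at day 7 and 0.314 over all libraries. Among simulated genes, drawn independently of each other, 25% of 2-fold changes were recovered. In the data 50 genes had an edgeR adjusted p from 0.05 to 0.06. Unadjusted p under 0.05 was reached by 1144 genes at day 7, 3164 at day 21, 2540 for the difference between days, 2850 for PBS and 2600 for LLC between days.

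The counts of 1 gene at day 7, 12 at day 21, 58 for the difference, 449 for PBS and 248 for LLC became 80, 1555, 722, 1109 and 813 with DESeq2, which also called Otop1 at day 7 (log2 1.14) and day 21 (-2.66). At an adjusted p under 0.1 the last 4 were 763, 445, 1020 and 680, and with a log2 change of at least 1, PBS and LLC had 235 and 79, fewer by construction. In 1 fit of all 18 libraries day 7 had 0 and day 21 had 2660, with Otop1 called at day 21 (-2.65), where the shared spread lies between those of the days. Day 21 had 58 with the newer deviance and 103 with the muscle covariate. Limma on log2(TPM + 1) and log2(TPM + 0.1) gave 61 and 78 at day 21, 21 and 23 for the difference, and 27 and 24 for LLC; without a filter LLC had 139. Without PBS and LLC libraries 3 day 7 had 0 (edgeR, beside 80 in DESeq2 on all libraries), and without PBS library 4 and LLC libraries 1 and 3 of day 21 the last 4 counts were 962, 1190, 3423 and 1789. The 15 lists at day 7 and 19 at day 21 became 0 and 0 with an estimated correlation, 0 and 4 with fry (neutrophil, red cell, Schwann cell and futile cycling), and 0 and 0 by exact permutation of scores (lowest adjusted p = 0.143 and 0.122).

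With 1 library left out the counts ranged from 0 to 3 genes at day 7, 0 to 1277 at day 21, 6 to 1222 for the difference, 41 to 1692 for PBS and 15 to 1036 for LLC, and from 12 to 16 lists at day 7 and 15 to 19 at day 21. Within each day Otop1 kept its side of the threshold, with log2 values of 1.02 to 1.28 and -3.04 to -2.32, and the correlation between days ran from 0.189 to 0.373 (0.234 over genes with at least 10 CPM, 0.201 on TPM). The paired block at day 7, fitted without LLC library 5, gave 1 gene and 12 lists, 11 of them among the 15. Leaving out that library alone gave the same 12 lists but 3 genes: Ifit3b and Dmrt2, called without it, were not called once the block was added. At day 21 samples of the same number correlated by -0.273, 0.302, 0.0925 and -0.158, so they were not treated as pairs. A block there, again without LLC library 5, gave 2 genes (1 of them among the 12), 20 lists and Otop1 at -3.51 (adjusted p = 0.136), against 9, 18 and -3.04 (adjusted p = 0.105) without that library alone. For the difference a block without LLC library 5 of each day gave 75 genes (37 higher, 38 lower), 23 of them among the 58. Other settings left these counts within 1.5 times, which does not mean that the same genes passed. Otop1 lost its call for the difference between days and within LLC without single libraries, as given with those comparisons. For named genes, 147 results had 3323 alternative values: 2882 on the same side of the threshold, 200 weaker, 241 stronger and 0 reversed.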

Other observations

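The lists and tests in this part were all chosen after the data were seen, and each list was tested with camera and adjusted over the 6 added lists. The mast cell, lymphatic and histone lists hold genes that had already passed at day 21, so their p-values are not independent of those calls. Mast cell genes were higher in LLC than in PBS at day 21 in 11 of 11 members (median log2 3.42, quartiles 2.44 and 4.13; adjusted p = 8.37e-12; adjusted p = 0.0254 with an estimated correlation), 4 of them past the edgeR threshold over all genes and 9 adjusted over the list alone. At day 7 the median was 0.26 (adjusted p = 0.0756). The effect differed between days by a median of 3.51 in 13 of 13 members (adjusted p = 5.07e-11; 0.0205 with an estimated correlation). Within PBS, day 21 was lower than day 7 by a median of 2.88 in 13 of 13, with 6 past the threshold over all genes (adjusted p = 5.08e-09; 0.0714 with an estimated correlation), and within LLC higher by 0.63 (adjusted p = 0.00613; 0.278). Genes of lymphatic endothelium moved the same way: at day 21, 8 of 9 were higher in LLC by a median of 1.89 (adjusted p = 4.31e-07; 0.0665 with an estimated correlation), Mmrn1 past the threshold over all genes and 7 adjusted over the list alone. They differed between days by 1.91 (adjusted p = 1.38e-05; 0.0302) and were lower at day 21 within PBS by 1.64 (adjusted p = 0.000225; 0.0966). At day 7 their median was 0.09 (adjusted p = 0.636) and within LLC it was 0.59 (adjusted p = 0.0211; 0.278). Lymphatic scores of day 21 PBS libraries 1 to 3 were -2.07 to -1.60 and that of library 4 was -0.495, against -0.492 or more in all others.

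Histone genes fell together in LLC at day 21, 9 of 9 lower by a median log2 of 1.2 with H2bc4 past the threshold over all genes and 9 adjusted over the list alone (adjusted p = 2.34e-09; 0.0254 with an estimated correlation). Their median at day 7 was 0.06 (adjusted p = 0.636). The effect was lower at day 21 than at day 7 in 10 of 10, with 3 past the threshold over all genes (adjusted p = 3.82e-11; 0.0205). Within LLC the fall from day 7 to day 21 had a median of -0.72 (adjusted p = 1.48e-10; 0.0268), with 6 past the threshold over all genes, and within PBS the median was 0.30 (adjusted p = 0.00228; 0.196). These messages mostly lack a poly(A) tail, so their values depend on how the libraries captured them. Scores were -1.09 to -0.414 in day 21 LLC and -0.328 to 0.764 in all other libraries. By exact two-sided permutation of the day 21 scores (n = 4 and 5), mast cell, lymphatic and histone lists each had p = 0.0159. That is the smallest p possible here, and adjusted over the added lists it was 0.0318. The neutrophil, B cell and red cell lists, fixed beforehand, had the same p but adjusted p = 0.122 over the fixed lists. Mast cell, lymphatic and histone lists hold genes already called in these libraries, so this permutation cannot serve as separate support.

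Genes of chylomicrons and enterocytes varied between libraries, with scores from -2.98 (day 21 LLC library 1) to 2.70 (day 21 PBS library 3). Their median log2 was 0.74 at day 7 (adjusted p = 4.16e-05; 0.428 with an estimated correlation), -0.28 at day 21 (adjusted p = 0.468), -1.49 for the difference between days (adjusted p = 0.00871; 0.41), 3.18 for day 21 against day 7 in PBS (adjusted p = 2e-05; 0.196), where 2 of 10 passed over all genes, and 1.61 in LLC (adjusted p = 0.0661). Genes of major urinary proteins and hepatocytes fell in LLC at day 7 (median -0.57, 9 of 11 lower, adjusted p = 0.00453; 0.616) and day 21 (-1.38, 11 of 11 lower, adjusted p = 0.000971; 0.335), 0 of them past the threshold over all genes, and had a score of -4.07 in day 21 LLC library 3. Between days their effect differed by -0.92 (adjusted p = 0.000955; 0.296), with -0.86 within LLC (adjusted p = 0.000181; 0.278) and a median of -0.08 against an upward test within PBS (adjusted p = 0.473). Tumour cell candidates had medians of 0.18 at day 7 (adjusted p = 0.636), 1.9 at day 21 (adjusted p = 0.291), 1.62 for the difference (adjusted p = 0.529), 0.43 within PBS (adjusted p = 0.473) and 2.25 within LLC (adjusted p = 0.0661), with a score of 4.32 in day 21 LLC library 1 and 1.14 or less elsewhere.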
